A study of Junco hyemalis with 48 samples.

How the data were processed

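The samples were growing tail feathers of the dark-eyed junco, a songbird whose outer tail feathers are white and whose inner ones are dark. Per the labels' protocols, tail feathers (rectrices) were plucked from both sides of the tail and the regrowing feathers were pulled 14 days later. The outer feather, the sixth rectrix, is called R6 here and is white along its whole length. The inner feather, the second rectrix, is called R2 and is dark along its whole length. The fourth rectrix, R4, has both colours, and its white and dark parts were separated by dissection before freezing. R6 and R2 were frozen whole. Dissection and feather position therefore differ together between R4 and the other feathers. The series text gives 7 birds with 3 to 8 feathers each, whereas the growth protocol in the labels gives 6 birds. The labels of the 48 libraries carry 7 animal identifiers, called birds A to G here, and these were used.

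Per the labels' protocols, RNA was extracted with an automated tissue kit, and stranded mRNA libraries were sequenced as 75 bp reads on a NextSeq. The submitters' processing notes name bcl2fastq, Trimmomatic 0.33, STAR 2.7.2b, featureCounts and Subread 1.6.0. Their order, settings and strand setting, the genome and the annotation are not given in the sources used here. The authors deposited 1 table of raw counts per gene model, with 1 column per library and no normalization. All columns were matched to samples by library name. The table holds 20808 gene models, and every identifier is the letter g followed by a number. The deposited file does not pair these identifiers with gene names, so no gene is named and no function is attached to any of them. With no annotation, overlapping gene models and near-identical copies could not be recognised, and the values of such gene models are uncertain.

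Left and right feathers of the same bird are not independent animals, so their counts were summed within each bird and group. This gave 26 profiles from 4 groups. R6 white had 13 libraries from 7 birds, the R4 white part 11 from 6, the R4 dark part 13 from 7, and R2 dark 11 from 6. Bird C had no library of the R4 white part and bird E none of R2. Before summing, the 22 left and right pairs were checked for a library deposited more than once. Identical columns would give a chi-square per gene against counting noise well below 1, and repeated sequencing of 1 library a value near 1. The chi-square per gene lay between 4.36 and 139.9. It was highest in the R4 dark pair of bird B, whose log2 CPM correlated across genes with r = 0.957, and next in that of bird D, at 94.9. Library totals lay between 12.99 and 53.46 M counts. The common biological coefficient of variation over profiles was 16.2%.

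Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersion, TMM factors and the default expression filter, which left 15844 gene models. The model held the group and the bird, and all 4 groups entered 1 fit and shared its estimate of the spread. Contrasts were R2 against R6 (whole feathers), the dark against the white part of R4 (within the feather), R2 against the R4 dark part, R6 against the R4 white part, and the difference between the first and the second contrast. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. All adjusted p-values come from edgeR unless DESeq2 is named. CPM values use TMM-scaled library sizes, and log2 CPM was computed with a prior count of 2. Standard errors (SE) of log2 folds were derived from the fold and its F statistic. Left and right feathers were tested over the 48 libraries with the bird and group combination as a block, over 14647 gene models.

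Pairing came from the same animal in each group. Deviations of same-bird profiles from their group means correlated across genes with a median r of 0.54 for R2 and R6, 0.28 for the R4 parts, 0.56 for R2 and the R4 dark part, and 0.48 for R6 and the R4 white part. Medians between different birds lay between -0.11 and -0.04. In 1 of the 4 contrasts the lowest same-bird value was below 0, at -0.21 between the R4 parts. RNA was extracted in 3 batches. Batch 1 held birds A and B, batch 2 birds C, D and E, and batch 3 birds F and G with the R4 white library of bird E. The bird term therefore also removes batch differences, except for that library.

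The genes called between R2 and R6 formed a higher set and a lower set. A set's score is its mean log2 CPM in a profile. Scores were compared between groups by an exact two-sided sign-flip permutation test over the 6 birds with both groups, for which the smallest possible p is 0.03125. Because the sets were chosen on the R2 and R6 profiles, they were also chosen on left feathers and measured on right feathers.

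The comparisons, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Among genes called with the same direction in every bird and a mean of at least 1 CPM, the rule took those with the largest fold, and it required a gene symbol. Since no identifier has one, that condition was dropped, and 2 gene models per direction are printed, from the comparison of R2 with R6. The 18 gene lists fixed beforehand, among them melanin synthesis, other cell types and stress, could not be matched to any identifier. Their tests and the share of counts in melanin genes were not run.

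Alternatives were DESeq2 1.42.0, RLE and upper quartile factors, no count filter, a filter at a mean of 5 CPM, no bird block, libraries left unsummed, left or right feathers alone, a fit of the compared groups alone, a 2-fold threshold, omission of the R4 white profile of bird E, and omission of each bird. Omission of the R4 dark profile of bird B, or of the R4 profiles of birds A and B, was added after seeing the data. The statistical procedure was tested on simulated counts with 200 gene models, of a mean of at least 1 CPM, changed by known folds. Counts were drawn independently for each gene model, with the same dispersion in all groups. For R2 against R6, over 15731 simulated gene models, 70.1% of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes were recovered, and 6 unchanged gene models were called. For the R4 parts, over 15730, these shares were 73.1%, 91.0% and 100%, with 5 unchanged gene models called. The simulated counts hold no structure shared across gene models, such as the differences in composition among the R4 libraries. They therefore do not give the error rate or the recovery in the real R4 comparison.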

Results

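The study profiled gene expression in growing tail feathers that were white, dark or both, in order to compare melanin-pigmented with unpigmented plumage. The 48 libraries came from 7 birds. The median library total was 18.1 M counts for R2, 18.6 M for the R4 white part, 20.5 M for the R4 dark part and 23.9 M for R6, and totals over all libraries ran from 12.99 to 53.46 M. A gene model at the median of those tested had 651 counts in the summed profile of a bird and group.

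The first question was how a dark inner feather differs from a white outer feather of the same bird. The gene model g3235 had the highest fold among those printed. It averaged 121 CPM ± 15.1 (SD, n = 6 birds) in R2 and 0.54 CPM ± 0.31 (SD, n = 7) in R6, a log2 fold of 8.06 (SE 0.66, adjusted p = 1.08e-06 in edgeR), and it was higher in R2 in 6 of 6 birds. The gene model g2687 averaged 120 CPM ± 9.15 (SD, n = 6) in R2 and 1.32 CPM ± 1.26 (SD, n = 7) in R6, with a log2 fold of 6.94 (SE 0.57, adjusted p = 1.08e-06), again higher in 6 of 6 birds. Both were lower in R6 by far more than the spread between birds. The gene models g3304 and g7321 went the other way. In R6, g3304 averaged 2.89 CPM ± 1.09 (SD, n = 7), against 0.69 CPM ± 0.24 (SD, n = 6) in R2, a log2 fold of -1.94 (SE 0.43, adjusted p = 0.0237). In R6, g7321 averaged 5.03 CPM ± 2.95 (SD, n = 7), against 1.34 CPM ± 0.66 (SD, n = 6) in R2, a log2 fold of -1.89 (SE 0.34, adjusted p = 0.00311). Both were lower in R2 in 6 of 6 birds, at levels of a few CPM that rest on 13 to 505 counts per profile. The call of g3304 was lost when bird A, D, F or G was left out, with adjusted p between 0.0757 and 0.142, and in left or right feathers alone. That of g7321 was lost without the bird block (adjusted p = 0.0893) and in left feathers alone (adjusted p = 0.145).

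Over all gene models, 200 of 15844 were called between R2 and R6, of which 128 were higher and 72 lower in the dark feather. The genes higher in R2 reached larger folds, with 26 above 4-fold and a median log2 fold of 0.67. The lower genes had a median of -1.28, and 10 of them were below by more than 4-fold. These 10 did not meet the rule for named genes, under which g3304 at -1.94 was the largest. That rule asks for a mean of at least 1 CPM and the same direction in every bird. With a filter at a mean of 5 CPM, 85 genes were called higher and 28 lower. All 128 higher genes and 70 of the 72 lower genes moved the same way in each of the 6 birds, which are the birds they were called on. Among genes chosen without regard to the values, chance gives 3.125%. Without the bird block, 85 genes were called. Without bird D 128 were called and without bird G 120. A fit of these 2 groups alone, in which the R4 parts do not enter the estimate of the spread, called 693, and left or right feathers alone called 81 and 77.

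**Figure D1:**
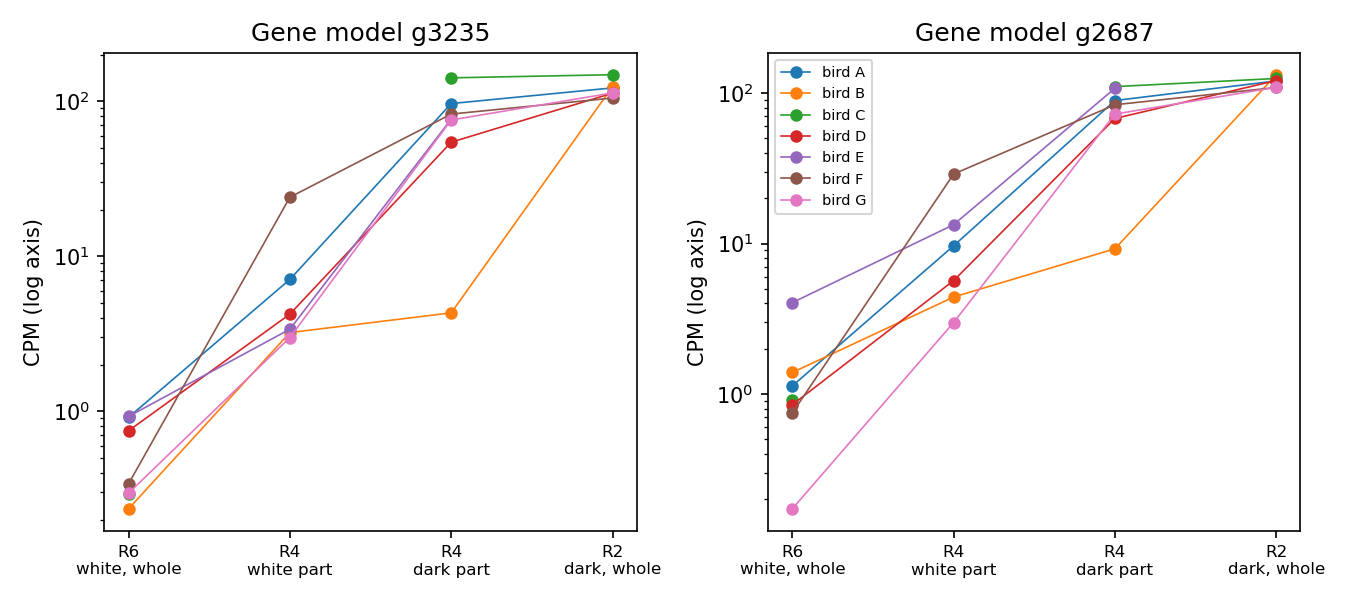
CPM of the gene models g3235 and g2687 on log axes, with 1 point per bird and group, and lines joining adjacent groups of the same bird. Both rise from R6 to R2 in every bird with both, and in bird B the R4 dark part stayed at 4.31 CPM for g3235 and 9.23 CPM for g2687.

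The second question was whether the dark and white parts of 1 feather differ in the same genes. Within R4, g3235 averaged 76.0 CPM ± 41.6 (SD, n = 7) in the dark part and 7.49 CPM ± 8.25 (SD, n = 6) in the white part, a log2 fold of 3.36 (SE 0.53, adjusted p = 0.00746), higher in the dark part in 6 of 6 birds. For g2687 the values were 77.2 CPM ± 34.0 (SD, n = 7) and 10.8 CPM ± 9.66 (SD, n = 6), a log2 fold of 2.98 (SE 0.49, adjusted p = 0.00850), also in 6 of 6 birds. Bird B had the smallest difference, since its R4 dark part held 4.31 CPM of g3235. Over 6 birds, the log2 difference of g3235 had an SD of 1.67 within R4 and 0.79 between whole feathers. For g2687 these SDs were 1.31 and 0.89. All groups shared 1 estimate of the spread, so SE and adjusted p-values of contrasts with R4 parts may be too small. Both calls were lost when bird A, D or G was left out, with adjusted p between 0.0665 and 0.0972, in right feathers alone, and in a fit of the R4 parts alone, with adjusted p = 0.983 for each. The gene models lower in R2 did not pass the test within R4. The log2 fold between the R4 parts was -0.03 (SE 0.41, adjusted p = 0.986) for g3304 and 0.18 (SE 0.34, adjusted p = 0.849) for g7321.

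In all, 117 gene models were called between the R4 parts, 76 higher and 41 lower in the dark part. Of these, 48 of the higher and 18 of the lower genes moved the same way in all 6 birds. Libraries of the R4 parts also differed in composition, with 11.3% to 25.1% of counts in the 20 most abundant gene models, against 13.3% to 16.01% in whole feathers. The count of calls changed with the samples used. It was 19 without the bird block, 1276 without the R4 dark profile of bird B, 1996 without bird B, 26 without A, 76 without C, 14 without D, 35 without E and 0 without G, where 1205 gene models had an unadjusted p below 0.05 in edgeR. A fit of the R4 parts alone called 0 gene models in edgeR. Of its 15143 gene models, 570 had an unadjusted p below 0.05, fewer than chance gives at that threshold. DESeq2 on all groups called 376.

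The 2 colour comparisons contrast different libraries of the same birds, and their calls overlapped in the genes higher in dark tissue. Both came from 1 fit with shared bird terms and 1 estimate of the spread, so the lists are not independent. Without the R4 dark profile of bird B, 301 gene models were called between R2 and R6 instead of 200. Of the 128 genes higher in R2 and the 76 higher in the R4 dark part, 37 were shared, where independent lists would share 0.614. The log2 folds of these 37 genes had a median of 1.30 between whole feathers and 0.87 within R4, and 33 of them had the larger fold between whole feathers. Among the genes lower in dark tissue, 2 were shared, where independent lists would share 0.186, and 0 genes were called in opposite directions. The shared total of 39 was 14 without the bird block, 102 without the R4 dark profile of bird B, between 6 and 17 without bird A, D or E, and 0 without bird G or when each pair of groups was fitted alone. Across genes, which are not independent replicates, the log2 folds of both comparisons correlated with r = 0.285 and rho = 0.085 over 15844 gene models, and with r = 0.807 over the 200 called between whole feathers.

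**Figure D2:**
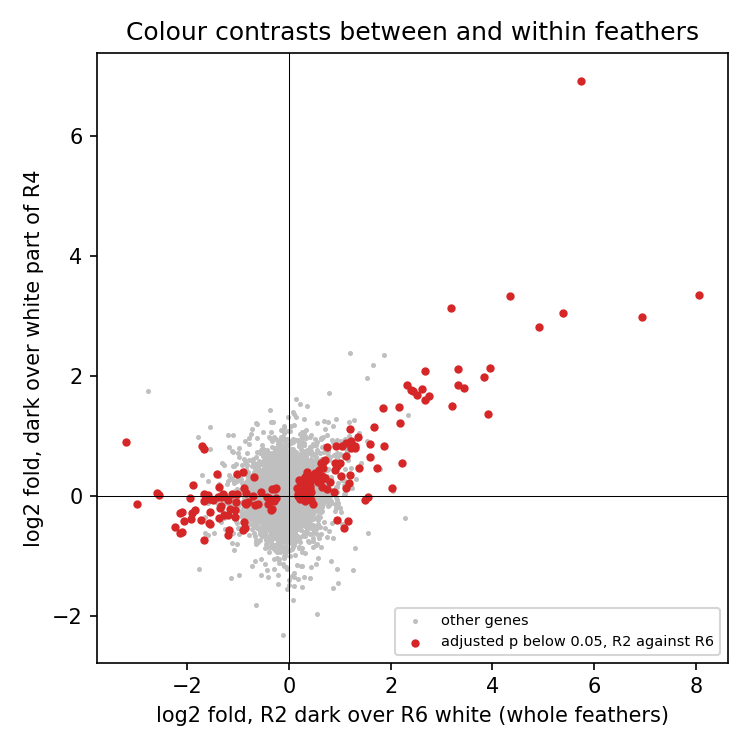
Log2 fold of R2 over R6 (horizontal axis) and of the R4 dark over the R4 white part (vertical axis), with 1 point per gene model tested. The 200 gene models called between R2 and R6 are red, and those on the right lie mostly above 0 on the vertical axis, with 112 of 128 positive, whereas those on the left have a median of -0.10, with 49 of 72 negative.

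The higher set of 128 genes scored 4.15 ± 0.07 mean log2 CPM (SD, n = 6) in R2, 3.77 ± 0.28 (SD, n = 7) in the R4 dark part, 3.14 ± 0.17 (SD, n = 6) in the R4 white part and 2.95 ± 0.10 (SD, n = 7) in R6. Between the R4 parts of the same bird it differed by 0.57 ± 0.32 (SD, n = 6), higher in the dark part in 5 of 6 birds (exact sign-flip permutation p = 0.0625, two-sided). Bird B differed by -0.01. By extraction batch, the mean difference was 0.38 in batch 1 and 0.61 in batch 3, with 2 birds each, and 0.60 in bird D, the only bird with both parts in batch 2. In bird E, whose parts were extracted in different batches, it was 0.82. Chosen on left feathers and measured on right feathers, the higher set held 60 genes, with a median log2 fold of 1.07 between whole feathers and 0.63 within R4.

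The lower set of 72 genes scored 1.98 ± 0.10 mean log2 CPM (SD, n = 7) in R6, 1.28 ± 0.28 (SD, n = 6) in the R4 white part, 1.16 ± 0.23 (SD, n = 7) in the R4 dark part and 0.79 ± 0.07 (SD, n = 6) in R2. Between the R4 parts it differed by -0.09 ± 0.38 (SD, n = 6), with 3 of 6 birds on each side (exact sign-flip permutation p = 0.75, two-sided). Bird B differed by -0.79, and without it the mean was 0.05 ± 0.18 (SD, n = 5), of the other sign. By extraction batch the mean difference was -0.26 in batch 1 and -0.06 in batch 3, with 2 birds each. It was -0.05 in bird D of batch 2, and 0.15 across batches in bird E. Its median log2 fold within R4 was -0.10, with 49 of 72 genes below 0, against -1.28 between whole feathers. Chosen on left and measured on right feathers, 21 genes had medians of -0.30 within R4, with 18 of 21 below 0, and -1.23 between whole feathers.

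**Figure D3:**
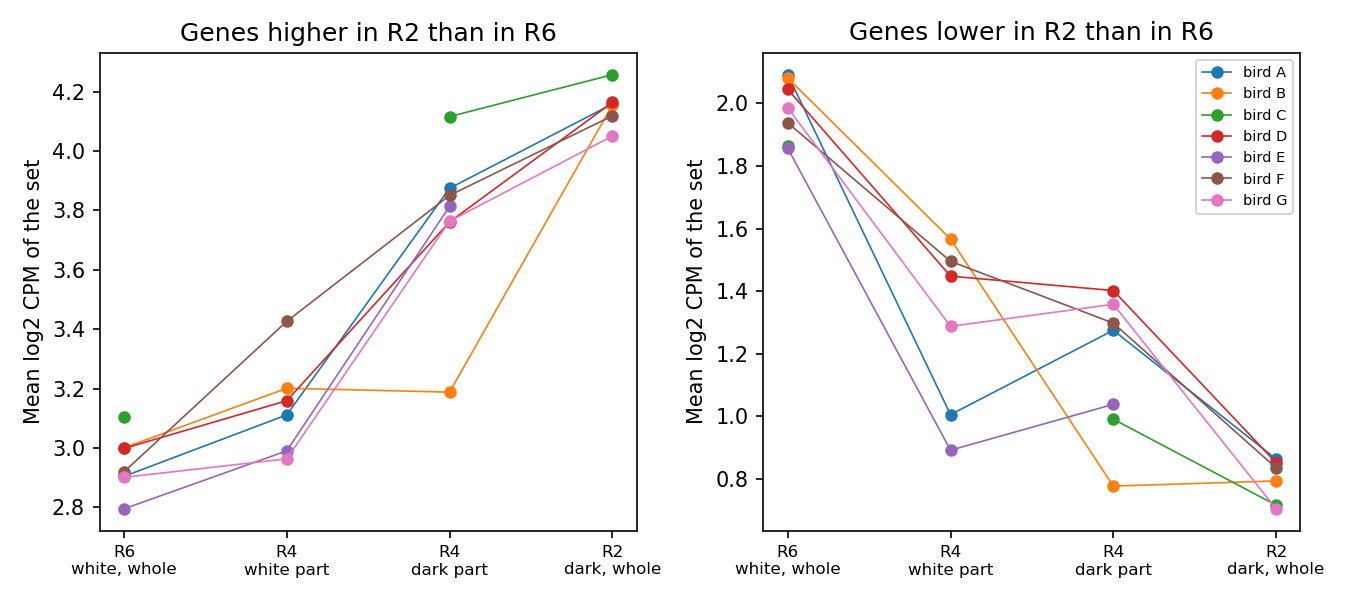
Mean log2 CPM of the 128 genes higher and the 72 genes lower in R2 than in R6, with 1 point per bird and group. Since the sets were chosen on R2 and R6, the end points differ by construction, and the points of interest are the R4 parts, which average 3.14 and 3.77 in the higher set and 1.28 and 1.16 in the lower set.

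Both remaining pairwise comparisons set a whole feather beside the R4 part of the same colour. Between the dark tissues, g3235 had a log2 fold of 0.94 for R2 over the R4 dark part (SE 0.48, adjusted p = 0.876) and g2687 one of 0.93 (SE 0.44, adjusted p = 0.844), so neither passed the test. Each was nevertheless higher in R2 in 6 of 6 birds. Without the R4 dark profile of bird B these log2 folds were 0.55 and 0.62. In all, 20 gene models were called, 13 higher and 7 lower in R2, with 12 and 7 of them moving the same way in all 6 birds. DESeq2 called 81. No gene model was called in edgeR without the bird block, where 371 had an unadjusted p below 0.05, without bird D, where 689 did, or in a fit of these 2 groups alone, where 856 did. Chance gives 792 of 15844 gene models at that threshold, so 371 and 689 lie below chance. The count of calls was 4 without bird A, 6 without B, 9 without E, 2 without F and 1 without G.

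Between the white tissues, g3235 was lower in R6 than in the R4 white part, with a log2 fold of -3.76 (SE 0.66, adjusted p = 0.0135), and g2687 one of -3.03 (SE 0.54, adjusted p = 0.0140), each in 6 of 6 birds. The gene model g7321 was higher in R6, with a log2 fold of 1.92 (SE 0.33, adjusted p = 0.00872). For g3304 it was 1.48 (SE 0.40, adjusted p = 0.120). Over the 21 alternatives the log2 folds of g3235 and g2687 stayed negative, at -4.51 to -2.97 and -3.62 to -2.44. The first 2 calls were lost without bird A, D, F or G, with adjusted p between 0.0538 and 0.111, in feathers of either side alone and in a fit of these 2 groups alone. That of g7321 was lost without the bird block (adjusted p = 0.264), without bird D or G, in left feathers alone and in a fit of these 2 groups alone. In all, 74 gene models were called, 60 higher and 14 lower in R6, and all of them moved the same way in 6 of 6 birds. Without the bird block 8 were called, without the R4 dark profile of bird B 316, without bird B 616, and without A, D, E, F or G between 17 and 44. The balance also changed without bird B, with 284 higher and 332 lower in R6. Without A, D, E, F or G most calls stayed higher in R6. Of the 13 genes higher in R2 and the 60 higher in R6 than in the R4 part of the same colour, 9 were shared, where independent lists would share 0.049.

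The last comparison tested whether the colour difference itself was the same between whole feathers and within R4. It differed for 21 gene models, 6 with a more positive and 15 with a more negative fold between whole feathers. For g3235 the log2 folds differed by 4.70 (SE 0.82, adjusted p = 0.0242) and for g2687 by 3.96 (SE 0.70, adjusted p = 0.0247). The 15 genes had a median log2 fold of -1.29 between R2 and R6 and of 0.15 between the R4 parts. The count was 3 without the bird block, 218 without the R4 dark profile of bird B and 291 without bird B. It fell to between 2 and 10 without any other bird.

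Left and right feathers gave a control comparison with no colour difference. No gene model was called in edgeR over the 22 pairs, where 495 had an unadjusted p below 0.05, and DESeq2 also called 0, with 535. Both numbers are below what chance gives over 14647 gene models. Within R6 alone 2 gene models were called.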

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

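All tests of explanations in this part were chosen after the results they bear on had been seen. A single bird stood apart from the others of its group in 8 of the 32 groups of values examined, where chance gives 1.6 if the groups were independent. They were not, since 3 of the 8 concern the R4 dark profile of bird B and 2 the R4 white profile of bird F. Bird B had a higher-set score of 3.19 in the R4 dark part, with the next bird at 3.76, and 9.23 CPM of g2687 there, with the next bird at 67.8. Its R2 exceeded its R4 dark part by 0.97 in the higher set, with the next bird at 0.40. Bird F had 24.0 CPM of g3235 in the R4 white part, with the next bird at 7.09. Its higher-set score in R6 minus that in the R4 white part was -0.51, with the next bird at -0.21. Bird E had 4.05 CPM of g2687 in R6, with the next bird at 1.39. Bird C had 0.56 CPM of g3304 in R6, with the next bird at 2.63. Bird G had 3.08 CPM of g7321 in the R4 white part, with the next bird at 1.40.

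For the R4 dark profile of bird B, the first pattern, an exchange of the labels of its 2 parts would put its white part at the level of dark parts, but that part scored 3.20, below the lowest other dark part at 3.76, so an exchange would leave the low score in place. Relabelling the parts of bird B alone raised the calls between R4 parts from 117 to 3902. Relabelling birds B and F gave 4808, although bird F had 82.7 CPM of g3235 in its dark and 24.0 CPM in its white part. A larger count therefore does not show which labels are right. Other values go with an exchange, since over genes not called between R2 and R6 the white part of bird B correlated at 0.229, 0.216 and 0.175 with the dark parts of birds A, F and E, between -0.0459 and 0.0587 with those of C, D and G, and between -0.00039 and 0.138 with white parts. Across genes, the deviation of the R4 dark profile of bird B from the bird's whole feathers correlated with that of the R4 white parts of birds A (r = 0.635), E (0.496), G (0.19), D (0.149) and F (-0.102), and with that of the 6 other dark parts between -0.181 and 0.0618. Its lower-set score of 0.78 was below those of the other dark parts, 0.99 to 1.40, and of the white parts, 0.89 to 1.57, and goes against white tissue like that of its own white part, at 1.57. White tissue of another makeup in this part, a wrong label for it, or a piece with another tissue makeup may each account for it and stay open, since over genes not called between R2 and R6 the median correlation was higher with white than with dark parts by 0.205 (exact permutation p = 0.0996, n = 5 and 6 parts), and no biological explanation was tested.

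The test of the difference in colour effect picked out 21 gene models, with g3235 at 4.70 and g2687 at 3.96 on the log2 scale. Of 16 splits that exchange R4 parts with whole feathers of the same colour bird by bird, the 1 real split gave 21 and the highest other 0. With 16 splits, no share under 0.05 can be reached.

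The smaller colour difference within R4 is the second pattern. For the higher set, measured on right feathers after choice on left, R6 over the R4 white part had a median log2 fold of -0.15, with 48 of 60 genes below 0, and R2 over the R4 dark part one of 0.31. Dark tissue left in the white part may give the white side, at -0.15, but does not lower the dark part, where 55 of 60 genes were above 0. Alone it therefore cannot give the whole pattern. Feather position along the tail may give both sides and stays open. White tissue left in the dark part, alone or beside dark tissue in the white part, was not tested for this pattern and stays open too. For the lower set, dark tissue in the white part would move it by the same share of the distance from R6 to R2 as the higher set, but the median share was larger by 54.5 percentage points ± 19.2 (SD, n = 5 birds), in 5 of 5 birds. These shares used the full sets, chosen on the same R2 and R6 profiles that set the distance. The choice may add to the gap, so the shares alone do not decide. Measured on right feathers after choice on left, R6 over the R4 white part had median log2 folds of 0.57 in the lower and -0.15 in the higher set. Those of R2 over R6 were -1.23 and 1.07. An effect of dissection that sets whole feathers above parts would put R2 above the R4 dark part. R2 over the R4 dark part was at -0.44, with 19 of 21 genes below 0, though these genes were chosen and measured in the same birds. By bird, the score of the full lower set differed by -0.39 ± 0.24 (SD, n = 6), above 0 in 1 of 6 birds (exact sign-flip permutation p = 0.0625, two-sided). That set was chosen on these same R2 profiles. The choice of genes low in R2 favours this direction, so these values cannot decide on dissection. Outside the set, 9 genes were higher in both whole feathers than in the R4 part of the same colour. A graded effect of tail position stays open, with R6 over the R4 white part at 0.57.

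Other assignments of the profiles were tried for each count. For R2 against R6, 1 of 32 splits that keep birds paired, the real one, gave 200 genes, and the highest other gave 1. Chance was thus excluded at the 0.05 level for this comparison taken alone, 1 of 32 being the smallest share possible. For R6 against the R4 white part, 1 of 32 gave 74, and the highest other gave 0. For R2 against the R4 dark part, 1 of 32 gave 20, and the highest other gave 0. Both shares are also the smallest possible, and lie under 0.05 only where each comparison is taken alone. No adjustment over the comparisons was made. In edgeR the count of 20 was itself 0 without the bird block, without bird D and in a fit of these 2 groups alone. There 371, 689 and 856 gene models had an unadjusted p below 0.05, of which 371 and 689 are fewer than chance gives. DESeq2 called 81. For the R4 parts, 7 of 32 splits gave 117 or more and the highest other gave 4808, with birds B and F exchanged, so chance was not excluded for this count. Each of the 6 other splits exchanged bird B. Bird A was never exchanged in these splits, so they show only that birds A and B were set opposite each other. They cannot place a structure of the samples around bird B rather than bird A, and a wrong label was not told apart from other structure. Of 68 splits per comparison that do not keep birds paired, 6 reached 117 for the R4 parts, with a highest of 2517, and 0 reached the real count in the other 3 pairwise comparisons. For left against right, all 12 of 12 splits gave 0, with a highest other of 0.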

How the results depend on the processing

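Omission of the R4 dark profile of bird B, omission of the R4 profiles of birds A and B, and the choice of sets on left feathers were added after the results were seen. Pairing was by animal, and the bird block raised each count of calls. In the order R2 against R6, R4 parts, R2 against the R4 dark part, R6 against the R4 white part, difference of colour effects, and overlap of both colour comparisons, the counts were 200, 117, 20, 74, 21 and 39. They were 85, 19, 0, 8, 3 and 14 with no replicate block, 314, 376, 81, 288, 131 and 76 in DESeq2, and 334, 406, 58, 477, 101 and 79 with libraries not summed, which treats feathers of 1 bird as independent. They were 81, 31, 13, 5, 8 and 13 in left feathers only, 77, 3, 0, 14, 1 and 3 in right feathers only, and 693, 0, 0, 22, 1 and 0 with only the groups compared. They were 98, 28, 9, 26, 13 and 17 at a 2-fold change or more, 301, 1276, 15, 316, 218 and 102 without the R4 dark profile of bird B, and 400, 665, 6, 248, 326 and 85 without the R4 profiles of birds A and B. Without the R4 white profile of bird E, there were 54 for the R4 parts, 8 for R2 against the R4 dark part, 8 for the difference and 25 for the overlap. At a mean of at least 5 CPM, 113 were called between R2 and R6, and with no low count filter 9 between R2 and the R4 dark part. Leaving out each bird in turn gave 120 to 192, 0 to 1996, 0 to 25, 17 to 616, 2 to 291 and 0 to 87. Several of these settings leave out samples or gene models, and otherwise the cause was not tested. Counts with RLE and upper quartile factors were within 1.5 times the main count. The count of 0 for R2 against the R4 dark part in right feathers only had 683 gene models at an unadjusted p below 0.05 in edgeR, fewer than chance gives. The left and right test called 2 within R6 alone.

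The folds of g3235 and g2687 between R2 and R6 stayed called under all 21 alternatives, at 7.77 to 8.70 and 6.69 to 7.45. Within R4 they stayed positive under all 21, at 3.04 to 3.90 and 2.68 to 3.46, and lost the call under 5. The fold of g3304 within R4, -0.03, changed sign in DESeq2 (0.0095), with only the groups compared (0.092), without the R4 dark profile of bird B (0.21), without the R4 profiles of birds A and B (0.11), and without single birds, over which it ran from -0.34 to 0.31. The fold of g7321 within R4, 0.18, was -0.092 in right feathers only and ran from -0.12 without bird A to 0.45 without bird B, and neither gene was called there. Other settings intended for the gene list tests and of the melanin share were not run, since no identifier has a gene name. Depth limits the lowest genes most, as g3304 rested on as few as 6 counts in a profile.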

Other observations

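The libraries of the R4 parts spread more widely than those of whole feathers on the first principal component. On the first, which held 20.2% of the variance, the 24 whole feather libraries lay between -21.6 and 2.08, and the 24 R4 libraries between -32.3 and 90.6. As labelled, the direction was not that of colour, although the label of the R4 dark part of bird B stays open. The dark part minus the white part, as a mean over sides, was -96.1 in bird A, -51.7 in bird E, -19.1 in bird G, 2.01 in bird D, 8.80 in bird F and 87.2 in bird B. In birds D and F the left and right feathers went opposite ways. In bird D the dark and white parts lay at -20.2 and 18.7 on the left, and at 31.3 and -11.5 on the right. In bird F they lay at -9.45 and -1.52 on the left, and at -1.95 and -27.5 on the right. Libraries high on this component also differed in composition. In the left and right libraries of the R4 white part of bird A, the 20 most abundant gene models held 25.1% and 21.3% of counts, with TMM factors of 0.797 and 0.879. In the R4 dark part of bird B these were 18.4% and 14.4%, with 0.886 and 0.932, and in the R4 dark part of bird A, at the low end, 11.7% and 11.98%, with 1.11 and 1.10. Whole feathers lay between 13.3% and 16.01%, with factors of 0.974 to 1.04. The left library of the R4 white part of bird A also had the lowest total, 12.99 M counts, and 15940 gene models with a count. On the second component, with 10.1% of the variance, whole feathers lay between -64.6 and 25.8 and R4 libraries between -38.4 and 20.1, and the bird held 70.5% of its variance. The value of -64.6 belonged to 1 library, the left R2 feather of bird G. The next lowest whole feather lay at -37.1, so without that library the ranges were alike.

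Without the R4 dark profile of bird B, an omission chosen after seeing the data, 583 genes were higher and 693 lower in the dark part of R4. Of the 583, 95 were also higher in R2 than in R6 and 3 were lower, where independent lists would share 6.77 and 4.31. Of the 693, 7 were also lower in R2 and 0 higher, where independent lists would share 5.12 and 8.05, so the 7 lie near chance. The median log2 fold between R2 and R6 was 0.05 for the 583 and 0.00091 for the 693, against 0.41 and -0.35 within R4. The 128 genes of the higher set had a median log2 fold within R4 of 0.34 without that profile, and 73 of them were called, against 0.32 and 37 with it.

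The 9 genes higher in both whole feathers than in the R4 part of the same colour had a median log2 fold of 1.20 over the dark part and 1.36 over the white part. Between R2 and R6 their median was 0.10, and 0 of the 9 were called there.

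The genes called between R2 and R6 often carried consecutive identifier numbers, a pattern tested after it was seen. There were 21 pairs with consecutive numbers and the same direction, 14 among the higher and 7 among the lower genes. In 10000 random sets of the same sizes the mean was 1.03 and the highest 7 (permutation p = 1e-04, the smallest that number of sets can give). Among gene models not called in any of the 4 pairwise comparisons, 11585 consecutive pairs had a median correlation over profiles of 0.18, against 0.00015 for random pairs. A hypothesis is that consecutive numbers mark related gene models, such as neighbours or pieces of 1 gene, and that the 21 pairs may make the 200 calls fewer independent units than they seem. The file does not state how the numbers were given.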
